A study of Mus musculus with 20 samples.

How the data were processed

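Mouse LβT2 gonadotrope cells on microcarrier beads were perifused and given GnRH at 10 or 100 nM in pulses of 2 min, once or at intervals of 118, 58 or 28 min, or continuously for 4 h. Total RNA was labelled with biotin and measured on 20 Affymetrix arrays. The deposited values are probe set signals, in intensity units on a linear scale, that the authors made with MAS5 as named in the submitters' processing notes. The version of MAS5, the chip description file and the scaling target are not given in the sources used here. The mean signal after trimming 2% off each end ran from 2501.25 to 2501.75 over the 20 arrays, so every array had been scaled to a common level, and this scaling was kept. Median signals ran from 705 to 836. All 20 columns were mapped to samples and 0 were left unmapped.

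Groups come from the sample titles, with 10 groups of 2 arrays. In 8 of the 20 samples the pulse number among the characteristics contradicts the title. The last 10 entries there repeat the order of the first 10, and the digit of the sample code goes with the pattern in each title, so titles were used and the characteristics became an alternative. The letters A and D in the sample codes mark 100 nM and unstimulated arrays, and B and C mark 10 nM arrays. The labels do not say that the arrays of a group come from separate cultures, so p-values measure only the spread between samples. Groups, comparisons, gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined.

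Signals were transformed as log2(signal + 166.8), where 166.8 is the 25th percentile of the table. Of 12488 probe sets 66 controls were left out, and 8491 were kept whose signal passed 427 (the 40th percentile) on at least 2 arrays. Limma 3.58.1 in R 4.3.3 fitted a group-means model to all 20 arrays (10 residual degrees of freedom, prior degrees of freedom 8.20, eBayes with an intensity trend). P-values are two-sided and adjusted with Benjamini-Hochberg within each comparison, at 0.05. The comparisons were all patterns of a dose against unstimulated, each pattern against unstimulated, the trend in log2 pulse number at each dose and its difference between doses, tonic against 8 pulses and its difference, and 100 nM against 10 nM over the patterns given at both. Trend values are changes per doubling of pulse number. RNA was taken at the end of 4 h, so pulse number goes with time since the last pulse. Chance gives about 425 of 8491 at an unadjusted p under 0.05.

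Gene symbols come from the platform annotation alone. It ties 10833 probe sets to 1 gene and 396 to several, and 1193 of the table are not in it; 0 symbols were changed. Each of 6216 genes is represented by its probe set of highest mean log2 signal, and 1765 tested probe sets carry a suffix for probes shared between transcripts. Named genes are the 8 largest rises and 8 largest falls among those past the threshold in each main comparison, up to 4 members of each list with the largest change where any member passed, and always Egr1, Nab1, Nab2, Lhb, Fshb, Cga and Gnrhr. Where no gene passed, the 3 of smallest p are named as values. The text gives a selection of the genes so named.

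The 14 gene lists are immediate early genes, feedback regulators of MAPK and Egr signalling, gonadotrope genes, GnRH receptor signalling, secretory granule and exocytosis, unfolded protein response, cholesterol synthesis, cell cycle, heat shock proteins, hypoxia and glycolysis, cytoskeleton and SRF targets, ribosomal proteins, interferon response, and other pituitary and non-pituitary cell types. They were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. Members were also adjusted over the list alone. A further 7 lists were written after the first results were seen.

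The letter was checked as a pairing from the correlation of residuals between groups. For B and C all 6 pairs of groups were over 0.1 (0.13 to 0.35), so the count of the 10 nM trend is given with the letter as a block as well. For A and D 14 of 15 pairs were over 0.1 (the lowest 0.08), which did not meet the rule. The correlation of arrays sharing a letter was 0.175. Replicate pairs correlated at 0.963 to 0.981 (median 0.974) and other pairs at a median of 0.963.

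The alternatives were quantile normalisation, equal array medians, a floor at 55.2 in place of the added constant, no filter, a stricter filter at 1362 (the 60th percentile), no intensity trend, the letter as a fixed or random block, only the compared groups, groups from the characteristics, only the 12 samples whose labels agree, leaving out each array, and the other probe sets of a gene. A fit without the 3 arrays of highest Gapdh 3' to 5' ratio was added after the data were seen, and for the lists in tonic against 8 pulses also fits without 8 pulses 100 nM A and at 10 nM alone. Ranges of adjusted p over all alternatives include the fit with groups from the characteristics. In it no called gene value kept its call, and it sets many of the upper ends.

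The fit was tested on simulated data with 8491 genes, of which 200 changed, in 5 rounds. For all 100 nM patterns it found 20.9% of changes of 0.5, 77.3% of 1 and 99.1% of 2 on the log2 scale, for all 10 nM patterns 21.2% of changes of 0.5, 81.2% of 1 and 98.5% of 2, for 1 pulse at 100 nM 8.06% of changes of 0.5, 56.1% of 1 and 96.4% of 2, for 8 pulses at 100 nM 9.25% of changes of 0.5, 56.1% of 1 and 95.2% of 2 and for 4 pulses at 10 nM 5.97% of changes of 0.5, 56.1% of 1 and 92.7% of 2. For the trend at 100 nM it found 91.3% of changes of 0.5, 99.7% of 1 and 100% of 2, at 10 nM 87.8% of changes of 0.5, 99.4% of 1 and 100% of 2 and for their difference 70.1% of changes of 0.5, 97% of 1 and 100% of 2. For tonic against 8 pulses it found 31% of changes of 0.5, 84.8% of 1 and 98.8% of 2, and for 100 nM against 10 nM 61.2% of changes of 0.5, 96.1% of 1 and 100% of 2. Between 4.30% and 7.27% of calls were false. Camera at the preset correlation, tested over 6216 genes, found 50 of 50 lists of 25 genes shifted by 0.3 and 0 of 50 unshifted ones. Noise was drawn independently for each gene and array, with no correlation between genes and no effect of the letter. The measured lists had estimated correlations of up to 0.545 (ribosomal proteins). The simulated rates of false calls and lists therefore do not cover correlated genes or arrays.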

Results

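LβT2 cells, a mouse pituitary gonadotrope line, were perifused for 4 h with medium alone or with gonadotropin-releasing hormone (GnRH), the hypothalamic peptide that drives gonadotropin secretion. GnRH was given at 100 nM as 1, 2, 4 or 8 pulses of 2 min or continuously (tonic), and at 10 nM as 1, 4 or 8 pulses or continuously. RNA taken at the end was measured on 20 Affymetrix arrays, 2 for each of the 10 groups. The 2% trimmed mean signal of the arrays ran from 2501.25 to 2501.75 and the median signal from 705 to 836. The number of arrays limits the precision of every value. Groups follow the sample titles. In 8 of the 20 samples the pulse number in another label field contradicts the title. With groups taken from that field, limma found 0 probe sets past the threshold in each of the 17 comparisons, with 72 to 1054 at an unadjusted p under 0.05. Changes below are log2 fold changes ± standard error, with adjusted p from limma. The number of arrays behind them is given for each comparison.

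GnRH at 100 nM raised early response genes and their feedback inhibitors strongly (10 arrays against 2 unstimulated ones). The largest rises were in Mmp12, the metalloelastase, at 3.07 ± 0.26 (8.40-fold, adjusted p = 1e-06), and Srxn1, sulfiredoxin, at 3.07 ± 0.20. Rrad, a GTPase that inhibits calcium channels, rose by 2.80 ± 0.24, and Rgs2, which dampens signalling from the Gq protein, by 2.46 ± 0.23. Egr1, the transcription factor through which GnRH acts on the Lhb promoter, rose by 2.35 ± 0.29 (adjusted p = 4.09e-05), Cidea by 2.37 ± 0.22, Egr2 by 2.24 ± 0.28 and the glucose transporter Slc2a1 by 2.07 ± 0.40. Falls were smaller and included the growth factor Vegfd (-1.41 ± 0.15), Ibtk (-1.38 ± 0.15), Hes6 (-1.34 ± 0.14), the helicase Recql5 (-1.34 ± 0.31), Dmtn (-1.44 ± 0.41, adjusted p = 0.0247) and Osbpl11 (-1.27 ± 0.16). In all, 1207 of 8491 probe sets passed, 541 higher and 666 lower; the split was 574 and 544 with quantile normalisation and 515 and 519 with array medians set equal. The count was 492 without the unstimulated array A and 363 without the unstimulated array D. A second probe set of Srxn1 (0.02 ± 0.19) and of Egr1 (0.32 ± 0.31) did not pass. With quantile normalisation Pdia4 (adjusted p = 0.0617) and Ebp (adjusted p = 0.137) lost their calls, Ebp also with array medians set equal (adjusted p = 0.0993; 0.0109 to 1 over all alternatives for the 2 genes). Without the 3 arrays of raised Gapdh ratio described below Dmtn, Inhbb, Cga, Pdia4 and Ebp lost theirs. Of the 44 called genes named here, without unstimulated A the calls of Slc2a1, Dmtn, Prl, Atf3, Dusp1, Inhbb, Cga, Ddit3, Manf, Ppp1r15a, Cd68, Pdia4 and Ebp were lost (adjusted p up to 0.369). Without unstimulated D the calls of Dmtn, Recql5, Prl, Inhba, Inhbb, Cga, Rab3d, Dnajc3, Manf, Plk1, Crhr1, Pdia4, Ebp, Rpl22 and Egln1 were lost (adjusted p up to 0.304). Leaving out 8 pulses 100 nM A, 2 pulses 100 nM A, 1 pulse 100 nM A, tonic 100 nM A, 1 pulse 10 nM B, 1 pulse 10 nM C, 4 pulses 100 nM D or 2 pulses 100 nM D lost the call of Ebp or Pdia4 (adjusted p up to 0.0553).

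Among the gene lists at 100 nM, 21 of 29 immediate early genes rose and none fell, with 24 risen when adjusted over the list alone (camera adjusted p = 7.15e-22, adjusted p = 0.0214 with an estimated correlation). Atf3 rose by 2.05 ± 0.38 and Fosl1 by 2.03 ± 0.18. Of 17 feedback regulators, 12 rose, or 13 adjusted over the list alone (camera adjusted p = 3.12e-12, adjusted p = 0.00251 with an estimated correlation). They include the corepressors of Egr proteins, Nab1 (1.44 ± 0.17) and Nab2 (1.56 ± 0.16), and the MAP kinase phosphatase Dusp1 (1.15 ± 0.21). Of 22 cytoskeletal genes and targets of serum response factor, 11 rose, or 13 adjusted over the list alone (camera adjusted p = 5.81e-08, adjusted p = 0.00175 with an estimated correlation), among them the actin-binding Tpm1 (1.57 ± 0.14), Cnn2 (1.44 ± 0.20) and Tpm4 (1.17 ± 0.11). In the unfolded protein response list, 9 of 19 rose and 1 fell, or 10 and 1 adjusted over the list alone (camera adjusted p = 1.3e-05, adjusted p = 0.0351 with an estimated correlation). Risen members were Ddit3 (1.15 ± 0.28), Dnajc3 (1.07 ± 0.23), Ppp1r15a (1.00 ± 0.24) and Manf (0.96 ± 0.22), while the disulfide isomerase Pdia4 fell (-0.79 ± 0.23). Further probe sets of Dnajc3 gave 0.55 ± 0.19 and 0.12 ± 0.22 and did not pass. Pdia4 and the members named below as moving against their list (Ebp, Egln1 and Rpl22) were chosen after their values were seen.

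Of 30 cell cycle genes 7 fell and 2 rose at 100 nM, or 8 and 2 adjusted over the list alone. The call of the list was lost with the estimate (camera adjusted p = 0.0223, adjusted p = 0.259 with an estimated correlation). The mitotic kinases Aurkb (-0.82 ± 0.15) and Plk1 (-0.67 ± 0.15) fell, and Cdkn1a, which inhibits the cycle, rose (1.70 ± 0.25). Of 15 cholesterol synthesis genes 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0273, adjusted p = 0.418 with an estimated correlation). Idi1 (1.30 ± 0.14) and Cyp51 (0.81 ± 0.14), enzymes of the pathway, rose, and Ebp, the sterol isomerase, fell (-0.45 ± 0.14). In the hypoxia and glycolysis list 2 of 19 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0289, adjusted p = 0.459 with an estimated correlation), and the fallen member was the oxygen sensor Egln1 (-0.58 ± 0.14). Of 19 ribosomal protein genes 5 rose and 1 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 3.38e-06, adjusted p = 0.272 with an estimated correlation). The fallen one was Rpl22 (-0.68 ± 0.17), whose second probe set gave 0.45 ± 0.21 and did not pass. With quantile normalisation the calls of the ribosomal (adjusted p = 0.67), hypoxia and glycolysis (adjusted p = 0.438) and heat shock lists (adjusted p = 0.438) were lost, the last also with array medians set equal (adjusted p = 0.053). Limma put 0 of 11 heat shock genes past the threshold, also 0 adjusted over the list alone (camera adjusted p = 0.0439, adjusted p = 0.272 with an estimated correlation). After 8 pulses (2 arrays against 2) 3 heat shock genes rose, or 5 adjusted over the list alone (camera adjusted p = 0.00164, adjusted p = 0.0833 with an estimated correlation). In the interferon response 2 of 9 genes fell, also 2 adjusted over the list alone (camera adjusted p = 0.294).

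Of 19 gonadotrope genes 2 rose and 1 fell over all 100 nM patterns (10 arrays against 2), or 2 and 2 adjusted over the list alone (camera adjusted p = 0.92). With tonic 100 nM GnRH 3 rose and 7 fell, the same numbers adjusted over the list alone, and after 8 pulses 2 and 4, or 4 and 5 (2 arrays against 2 each; camera adjusted p = 0.641 and 0.768). Over all 100 nM patterns Inhba, which encodes the activin and inhibin βA chain, rose by 0.96 ± 0.23, and Inhbb, the βB chain, fell (-0.82 ± 0.22). Cga, the common α-subunit of the gonadotropins, rose by 0.51 ± 0.15 (adjusted p = 0.032), but stood at -0.00115 with quantile normalisation. That setting gives the brightest probe sets nearly the same value on every array. Cga is among the brightest (mean log2 signal 16.4 for its second probe set), so that setting cannot decide on its change. Lhb, the LH β-subunit, was at 0.04 ± 0.15 (adjusted p = 0.887) and the GnRH receptor gene Gnrhr at -0.17 ± 0.20 (adjusted p = 0.634), and neither passed. Gnrhr was lower with tonic 100 nM GnRH (-0.75 ± 0.26, adjusted p = 0.048, 2 arrays against 2). This call was lost with quantile normalisation (adjusted p = 0.0842) and with array medians set equal (adjusted p = 0.0936). Its adjusted p ran from 0.0266 to 1 over all alternatives. Leaving out 1 pulse 100 nM A, tonic 100 nM A, unstimulated A, 8 pulses 10 nM B, 4 pulses 10 nM B, 1 pulse 10 nM B, 8 pulses 10 nM C, 4 pulses 10 nM C, 1 pulse 10 nM C, 8 pulses 100 nM D, 1 pulse 100 nM D, tonic 100 nM D or unstimulated D lost the call of Gnrhr (adjusted p up to 0.266). Fshb, the FSH β-subunit, lay below the signal filter and was not tested, with group mean signals from 213 to 401. Of 17 exocytosis genes 3 rose, among them Syt4 (1.40 ± 0.16) and Snap25 (1.05 ± 0.17), and 3 fell, among them Rab3d (-0.75 ± 0.15), the same numbers adjusted over the list alone (camera adjusted p = 0.294). Of 25 genes of GnRH receptor signalling 1 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.294). In the list of other cell types, 2 of 14 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.294). These were the corticotrope receptor gene Crhr1 (1.53 ± 0.29), the macrophage marker Cd68 (1.34 ± 0.24) and prolactin, Prl (-1.27 ± 0.29).

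By pattern at 100 nM (2 arrays against 2 each), Egr1 stood at 0.69 ± 0.38 after 1 pulse, 1.02 ± 0.38 after 2, 2.41 ± 0.38 after 4, 3.87 ± 0.38 after 8 and 3.76 ± 0.38 with tonic GnRH. It passed for 4 pulses, 8 pulses and tonic. Nab1 stood at 1.12 ± 0.22, 1.57 ± 0.22, 1.73 ± 0.22, 1.53 ± 0.22 and 1.24 ± 0.22 in that order. It passed for all but 1 pulse (adjusted p = 0.0915; 0.00981 with the letter as a block; 0.00981 to 1 over all alternatives). Limma found 0 probe sets after 1 pulse, with 664 at an unadjusted p under 0.05 where chance gives about 425. With the letter as a fixed block it found 21, with a random block 14 and with quantile normalisation 12, and 3 without the unstimulated array A and 1 without 1 pulse D. It found 53 after 2 pulses (47 higher), 1268 after 4 (528 higher), 1215 after 8 (556 higher) and 1735 with tonic GnRH (729 higher). With array medians set equal the numbers higher and lower were 33 and 2, 492 and 590, 551 and 478, and 764 and 768 in that order. The counts rest on single arrays. Without the unstimulated array A they were 11, 708, 744 and 1109 for 2, 4 and 8 pulses and tonic, and without D they were 17, 451, 611 and 1108. Without its own array A the count for 2 pulses was 14 and for 8 pulses 678; without its own array D it was 13 for 2 pulses, 203 for 4 and 1086 for tonic. The Gapdh 3' to 5' signal ratio, a sign of RNA quality, was 1.69 on the 8 pulse array A and 1.21 and 1.23 on the 4 pulse arrays A and D, against 0.900 to 1.08 on the other 17 arrays. For 8 pulses the count was 716 without these 3 arrays.

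**Figure D1:**
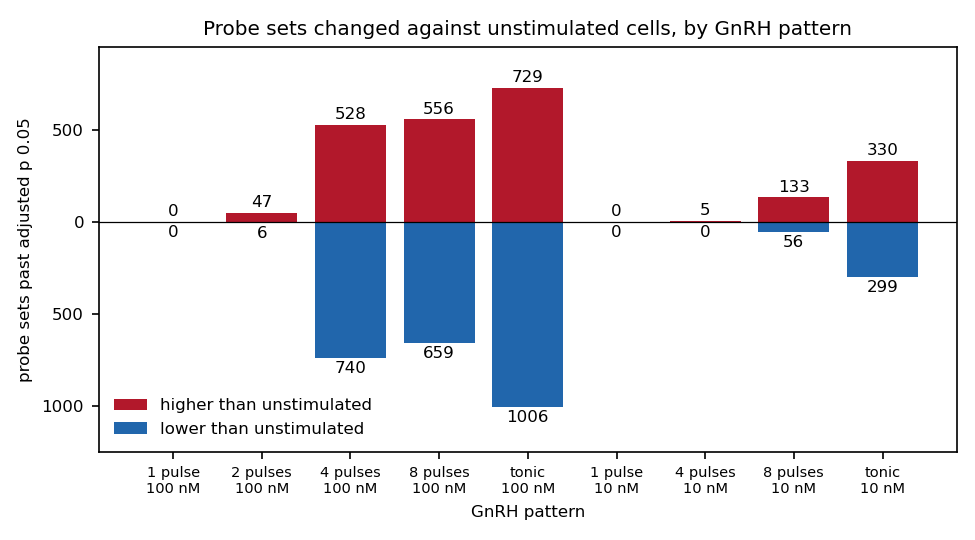
Number of probe sets past an adjusted p of 0.05 in each GnRH pattern against unstimulated cells (2 arrays against 2), with higher probe sets drawn upward and lower ones downward. The total with limma is 0 after 1 pulse at either dose (up to 21 at 100 nM under the alternatives given in the text) and reaches 1735 with tonic 100 nM and 629 with tonic 10 nM GnRH.

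**Figure D2:**
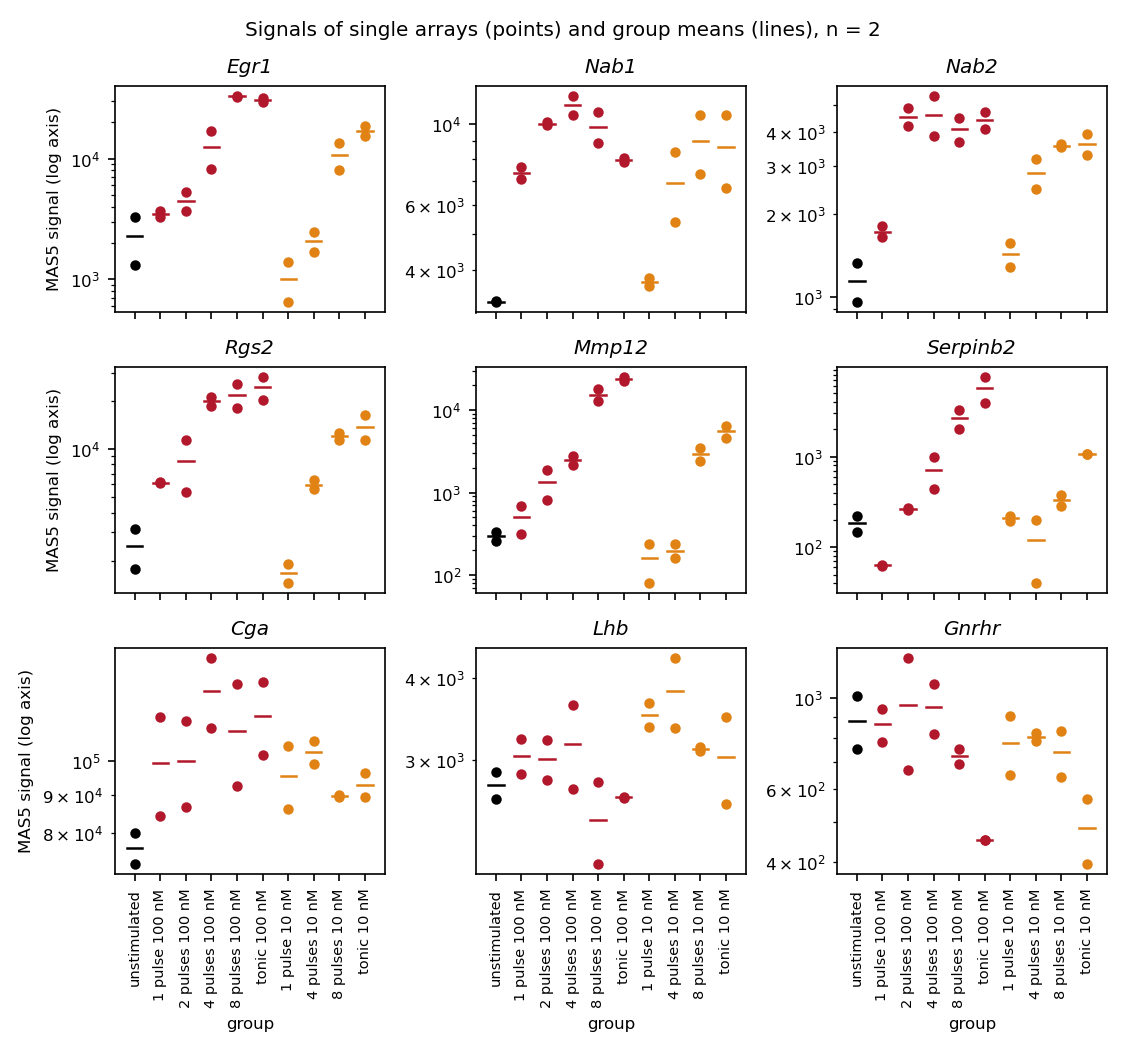
MAS5 signals on a log axis for 9 genes in the 10 groups, with 1 point per array and a line at the mean of the 2 arrays. Within each dose Egr1 is highest with 8 pulses and tonic GnRH, and Nab1 passed from 2 pulses on at 100 nM.

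At 10 nM (8 arrays against 2) Rrad rose by 1.81 ± 0.25, Srxn1 by 1.81 ± 0.21, Slc2a1 by 1.78 ± 0.41, Egr2 by 1.51 ± 0.29, Rgs2 by 1.38 ± 0.24, Mmp12 by 1.37 ± 0.26 and Cidea by 1.36 ± 0.23, and the tubulin gene Tubb6 by 1.30 ± 0.15. The transcription factor Tcf4 (-1.07 ± 0.23), the kinase Map2k6 (-0.97 ± 0.19), Smarce1 (-1.08 ± 0.19), Pag1 (-1.07 ± 0.23), Ibtk (-1.04 ± 0.16) and Vegfd (-0.94 ± 0.15) fell. Egr1 was at 1.03 ± 0.30 and did not pass (adjusted p = 0.0807; 0.0474 without the unstimulated array D; 0.0474 to 0.933 over all alternatives), while Nab1 (0.97 ± 0.18) and Nab2 (1.14 ± 0.16) rose. Lhb (0.27 ± 0.15), Cga (0.32 ± 0.15) and Gnrhr (-0.29 ± 0.21) did not pass. Second probe sets of Srxn1 (0.019 ± 0.19), Map2k6 (-0.59 ± 0.23) and Crem (0.74 ± 0.26) did not pass. Of 8491 probe sets 162 passed, 106 higher and 56 lower; with array medians set equal the split was 104 and 22. The unstimulated arrays carry the replicate letters A and D, and all 10 nM arrays B and C. GnRH and letter therefore cannot be separated in any comparison of 10 nM with unstimulated cells, by pattern and for the lists as well. The trend at 10 nM stays within B and C. The count was 34 without the unstimulated array A, 36 without D, 107 without 8 pulses B, 85 without 1 pulse B, 105 without tonic B and 93 without 4 pulses C. With array medians set equal Tcf4 (adjusted p = 0.0502) and Idi1 (adjusted p = 0.075) lost their calls, and with the letter as a random block Cdkn1a (adjusted p = 0.0533) and Idi1 (adjusted p = 0.0536; 0.00709 to 0.989 over all alternatives for the 3 genes). Without the 3 arrays of raised Gapdh ratio Idi1 and Cdkn1a lost theirs as well. Of the 26 called genes named here, without unstimulated A the calls of Rrad, Slc2a1, Egr2, Rgs2, Mmp12, Smarce1, Pag1, Tcf4, Map2k6, Vegfd, Crem, Nab1, Nab2, Manf, Creld2, Idi1, Cdkn1a, Tpm1, Cnn2, Tpm4 and Syt4 were lost (adjusted p up to 0.486). Without unstimulated D the calls of Mmp12, Cidea, Smarce1, Pag1, Tcf4, Ibtk, Map2k6, Vegfd, Nab1, Manf, Creld2, Idi1, Cdkn1a, Cnn2 and Syt4 were lost (adjusted p up to 0.258). Leaving out 4 pulses 100 nM A, 1 pulse 100 nM A, tonic 100 nM A, 8 pulses 10 nM B, 1 pulse 10 nM B, tonic 10 nM B, 8 pulses 10 nM C, 4 pulses 10 nM C, 1 pulse 10 nM C, tonic 10 nM C, 4 pulses 100 nM D, 1 pulse 100 nM D or tonic 100 nM D lost the call of Cdkn1a, Creld2, Idi1 or Slc2a1 (adjusted p up to 0.0834).

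Of 29 immediate early genes 6 rose at 10 nM, among them Crem (1.10 ± 0.20), or 15 adjusted over the list alone (camera adjusted p = 5.26e-12, adjusted p = 0.0828 with an estimated correlation, so the call was lost). The feedback list had 3 risen of 17, also 3 adjusted over the list alone (camera adjusted p = 1.03e-06, adjusted p = 0.0272 with an estimated correlation). In the unfolded protein response 2 of 19 rose, Manf (1.08 ± 0.22) and Creld2 (0.69 ± 0.16), or 5 adjusted over the list alone (camera adjusted p = 1.85e-06, adjusted p = 0.0296 with an estimated correlation). Of 22 cytoskeletal genes 3 rose, Cnn2 (1.02 ± 0.21), Tpm1 (0.94 ± 0.15) and Tpm4 (0.70 ± 0.11), or 6 adjusted over the list alone (camera adjusted p = 3.06e-07, adjusted p = 0.00239 with an estimated correlation). In cholesterol synthesis 2 of 15 rose, Cyp51 (0.94 ± 0.14) and Idi1 (0.56 ± 0.14), also 2 adjusted over the list alone (camera adjusted p = 8.87e-07, adjusted p = 0.0917 with an estimated correlation, so the call was lost). Calls were lost with the estimate as well for hypoxia and glycolysis (1 risen, 3 adjusted over the list alone; camera adjusted p = 4.39e-05, adjusted p = 0.323 with an estimated correlation) and ribosomal proteins (camera adjusted p = 1.14e-05, adjusted p = 0.323 with an estimated correlation), of which limma put 0 past the threshold, also 0 adjusted over the list alone. With quantile normalisation the ribosomal call was lost too (adjusted p = 0.903), and the cell cycle (adjusted p = 0.0118) and heat shock lists (adjusted p = 0.0382) were called lower. In the main fit neither was called (camera adjusted p = 0.236 and 0.687, adjusted p = 0.48 and 0.754 with an estimated correlation). The estimate was not run with quantile normalisation. Cdkn1a rose (1.05 ± 0.26) and Syt4 rose (0.74 ± 0.16), each the only called member of its list. Adjusted over the list alone, 1 cell cycle gene rose and 2 fell, and 1 secretory gene rose and 1 fell.

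By pattern at 10 nM (2 arrays against 2), Egr1 stood at -1.01 ± 0.38 after 1 pulse, -0.03 ± 0.38 after 4, 2.23 ± 0.38 after 8 and 2.92 ± 0.38 with tonic GnRH, and Nab1 at 0.17 ± 0.22, 1.00 ± 0.22, 1.38 ± 0.22 and 1.32 ± 0.22. Both passed after 8 pulses and with tonic GnRH. The 8 pulse call of Egr1 was lost without the unstimulated array A or 8 pulses B (adjusted p up to 0.0697) and that of Nab1 without 8 pulses C (adjusted p = 0.0507). Limma found 0 probe sets after 1 pulse, with 708 at an unadjusted p under 0.05, 2 without the unstimulated array A and 1 without D. Of 29 immediate early genes it put 0 past the threshold after 1 pulse, also 0 adjusted over the list alone, with the list shifted down (median -0.217; camera adjusted p = 0.0122, adjusted p = 0.75 with an estimated correlation, so the call was lost). After 4 pulses it put 0 past, or 2 adjusted over the list alone, with the list shifted up (median 0.122; camera adjusted p = 0.0328, adjusted p = 0.622 with an estimated correlation, lost as well). After 4 pulses 5 passed, all higher: Nab2 (1.19 ± 0.20), Gch1, the first enzyme of tetrahydrobiopterin synthesis (1.23 ± 0.20), 1 probe set of Pdlim7 (0.96 ± 0.16; 0.54 ± 0.24, not past, for the brightest one of that gene), Tubb6 (1.18 ± 0.18) and Sertad1 (1.09 ± 0.17), with adjusted p from 0.0211 to 0.0267. These were chosen after their values were seen. With quantile normalisation 7 were higher and 1 lower. Their number was 26 without 4 pulses B, 0 without 4 pulses C and 0 without the unstimulated array D, and Nab2, Gch1 and Sertad1 lost their calls without the unstimulated array A (adjusted p up to 0.182). After 8 pulses 189 passed, 133 higher and 56 lower (157 and 31 with array medians set equal), and with tonic GnRH 629, 330 higher and 299 lower (323 and 206 with array medians set equal). Without the unstimulated array A these counts were 84 and 251, and without D 81 and 345. Without their own array B they were 62 and 175, and for 8 pulses without C 68.

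**Figure D3:**
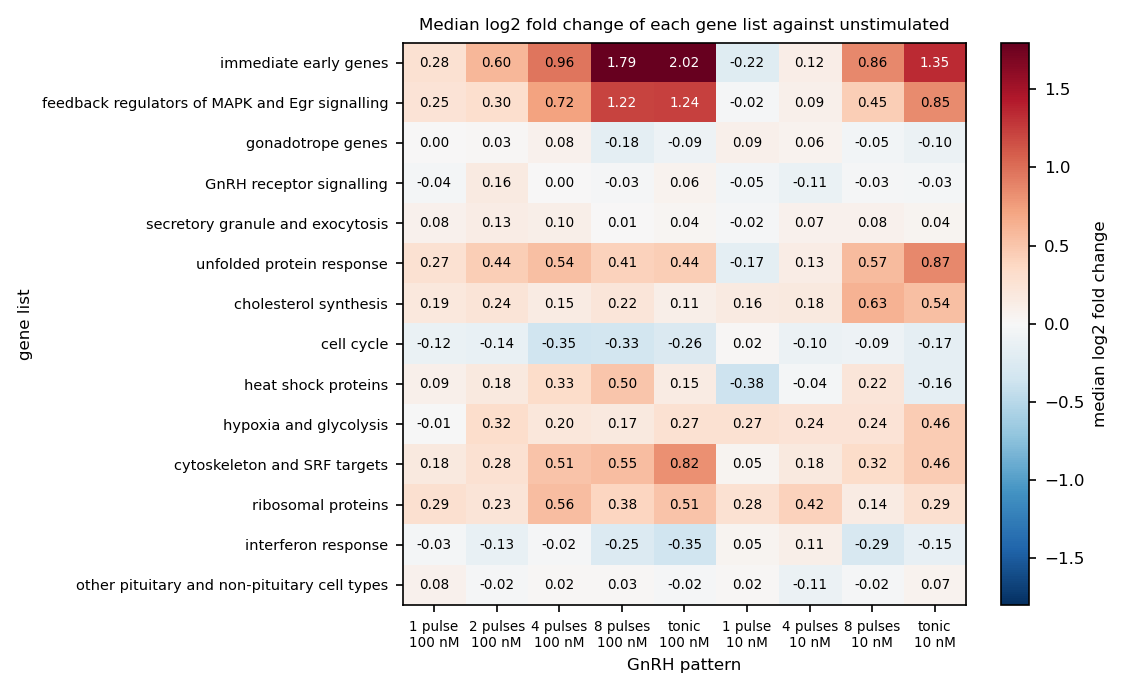
Median log2 fold change of the tested members of each of the 14 gene lists (vertical axis) in each GnRH pattern against unstimulated cells (horizontal axis, 2 arrays against 2), written in each field and coloured from blue (lower) to red (higher). The immediate early genes are highest with 8 pulses and tonic 100 nM GnRH.

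The series title asks how gene expression follows GnRH pulses, and the trend over 1, 2, 4 and 8 pulses at 100 nM (2 arrays each) gives the change per doubling of pulse number. Mmp12 rose by 1.46 ± 0.10 per doubling, Serpinb2, an inhibitor of plasminogen activators, by 1.17 ± 0.11, Egr1 by 1.09 ± 0.12 (adjusted p = 1.8e-05), Angpt2 by 0.87 ± 0.10 and Srxn1 by 0.83 ± 0.08. Rrad rose 2.30-fold per doubling (log2 standard error 0.10). Recql5 (-0.64 ± 0.13), Setd4 (-0.52 ± 0.12) and the acetyltransferase Kat2a (-0.42 ± 0.09) fell. Nab2 rose by 0.35 ± 0.06, while Nab1 was at 0.14 ± 0.07 and did not pass (adjusted p = 0.27). The pituitary transcription factor genes Nr0b1 (-0.31 ± 0.05) and Pitx1 (-0.23 ± 0.07) fell, and Lhb (-0.09 ± 0.06), Cga (0.07 ± 0.06) and Gnrhr (-0.06 ± 0.08) did not pass. Of 8491 probe sets 585 passed, 312 rising and 273 falling; with array medians set equal the split was 323 and 165. RNA was taken at the end of 4 h, so more pulses also meant less time since the last one. The second probe sets of Egr1 (-0.07 ± 0.13) and Srxn1 (0.041 ± 0.08) did not pass. The count was 308 without 8 pulses A, 294 without 1 pulse A and 250 without 1 pulse D. Of the 31 called genes named here, without 1 pulse 100 nM A the calls of Setd4, Atf3, Rab3d, Prkce, Vegfa and Slc2a1 were lost (adjusted p up to 0.19). Without 8 pulses 100 nM D the calls of Setd4, Pitx1, Prkce and Slc2a1 were lost (adjusted p up to 0.23). Without 1 pulse 100 nM D the calls of Kat2a, Pitx1, Syt4, Cdkn1a, Ccnb2 and Slc2a1 were lost (adjusted p up to 0.299). Leaving out 8 pulses 100 nM A, 4 pulses 100 nM A, 2 pulses 100 nM A, tonic 100 nM A, 8 pulses 10 nM B, 1 pulse 10 nM B, 8 pulses 10 nM C, 1 pulse 10 nM C, 4 pulses 100 nM D or tonic 100 nM D lost the call of Ccnb2, Pitx1, Slc2a1 or Vegfa (adjusted p up to 0.0885).

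Of the 29 immediate early genes 20 rose with pulse number at 100 nM, or 24 adjusted over the list alone (camera adjusted p = 3.37e-29, adjusted p = 0.00834 with an estimated correlation), among them Crem (0.76 ± 0.08), Ier3 (0.76 ± 0.07) and Atf3 (0.74 ± 0.16). Of 17 feedback regulators 9 rose, or 11 adjusted over the list alone (camera adjusted p = 6.49e-11, adjusted p = 0.00394 with an estimated correlation), with Rgs2 at 0.66 ± 0.09 and Dusp1 at 0.53 ± 0.09. Of 22 cytoskeletal genes 7 rose, or 10 adjusted over the list alone (camera adjusted p = 3e-09, adjusted p = 8.96e-04 with an estimated correlation), with Krt18 at 0.54 ± 0.08, Cnn2 at 0.50 ± 0.08, Tpm1 at 0.40 ± 0.06 and Tpm4 at 0.37 ± 0.05. In the heat shock list 1 of 11 rose, Hsph1 (0.38 ± 0.06), or 4 adjusted over the list alone (camera adjusted p = 5.49e-05, adjusted p = 0.0316 with an estimated correlation). In hypoxia and glycolysis 5 of 19 rose, also 5 adjusted over the list alone, with Slc2a1 (0.62 ± 0.16), Vegfa (0.42 ± 0.09) and Ndrg1 (0.32 ± 0.06). The call was lost (camera adjusted p = 0.0176, adjusted p = 0.474 with an estimated correlation). In the cell cycle list 2 fell, among them the cyclin gene Ccnb2 (-0.21 ± 0.05), and 1 rose, the inhibitor Cdkn1a (0.51 ± 0.10), or 7 and 1 adjusted over the list alone. Its call was lost as well (camera adjusted p = 0.0187, adjusted p = 0.226 with an estimated correlation). The unfolded protein response (1 risen, also 1 adjusted over the list alone; camera adjusted p = 0.0114, adjusted p = 0.225 with an estimated correlation) and ribosomal proteins (1 risen, 0 adjusted over the list alone; camera adjusted p = 0.0114, adjusted p = 0.474 with an estimated correlation) lost theirs too. With quantile normalisation these 2 (adjusted p = 0.0647 and 0.58) and hypoxia and glycolysis (adjusted p = 0.139) had no call either. Called members of other lists included Idi1 (0.34 ± 0.06), the kinase Prkce (-0.31 ± 0.07), Syt4 (0.31 ± 0.06) and Rab3d (-0.31 ± 0.06). Adjusted over the list alone, 1 cholesterol gene rose and 3 fell, 0 and 1 in GnRH receptor signalling, and 3 and 4 in the secretory list. The arrays with a raised Gapdh 3' to 5' ratio (1.69, 1.21 and 1.23) had 8 or 4 pulses at 100 nM and so moved with all these groups. By the actin 3' to 5' ratio 1 pulse 100 nM D (3.30) was close to 4 pulses 100 nM A (3.32). Without the 3 arrays of raised Gapdh ratio the trend at 100 nM ran over 1, 2 and 8 pulses, with array D alone for 8 pulses. Fewer probe sets passed, and Nab2, Pitx1, Cdkn1a, Ccnb2 and Vegfa lost their calls.

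At 10 nM, where the Gapdh ratio stayed between 0.900 and 1.01, the trend over 1, 4 and 8 pulses (2 arrays each) was led by Egr1 (0.99 ± 0.12 per doubling, adjusted p = 2.59e-04), Mmp12 (0.95 ± 0.11), the orphan receptor Nr4a1 (0.94 ± 0.18), Rrad (0.94 ± 0.10), Egr2 (0.92 ± 0.12), Rgs2 (0.91 ± 0.10) and Srxn1 (0.91 ± 0.09). The actin 3' to 5' ratio was less even. It was 3.64 on 1 pulse C, against 2.23 to 2.83 on the other arrays of this trend. Zbtb17 (-0.56 ± 0.13), Mast3 (-0.55 ± 0.13), Recql5 (-0.54 ± 0.13), Sema6b (-0.54 ± 0.11), Hes6 (-0.41 ± 0.06) and Maf1, a repressor of RNA polymerase III (-0.39 ± 0.06), fell. Nab1 rose by 0.41 ± 0.07 and Nab2 by 0.41 ± 0.07, and Lhb (-0.04 ± 0.06), Cga (-0.02 ± 0.06) and Gnrhr (-0.01 ± 0.08) did not pass. Second probe sets of Egr1 (0.15 ± 0.13), Mmp12 (0.49 ± 0.13, adjusted p = 0.0527), Srxn1 (-0.024 ± 0.08) and Atf3 (0.51 ± 0.14) and 1 of 2 further ones of Pdia6 (0.31 ± 0.13) did not pass. Of 8491 probe sets 178 passed, 132 rising and 46 falling (140 and 25 with array medians set equal). With the replicate letter as a block 464 passed. The other values, list results and lost calls of this trend come from fits without the block. The count was 89 without 8 pulses B, 80 without 8 pulses C, 69 without 1 pulse B and 39 without 1 pulse C. With a floor in place of the added constant Zbtb17, Mast3, Recql5 and Sema6b lost their calls (adjusted p = 0.0553 to 0.073). Zbtb17 also lost its call with quantile normalisation (adjusted p = 0.0593) and array medians set equal (adjusted p = 0.0617; 0.00526 to 1 over all alternatives for the 4 genes). Of the 27 called genes named here, without 8 pulses 10 nM B the calls of Atf3, Zbtb17, Sema6b, Dusp16, Pdia6, Msmo1 and Hsph1 were lost (adjusted p up to 0.176). Without 1 pulse 10 nM B the calls of Zbtb17, Mast3, Recql5, Sema6b, Dusp16, Xbp1, Pdia6, Msmo1, Hsph1 and Syt4 were lost (adjusted p up to 0.298). Without 8 pulses 10 nM C the calls of Zbtb17, Mast3, Recql5, Nab1, Xbp1, Pdia6 and Syt4 were lost (adjusted p up to 0.273). Without 1 pulse 10 nM C the calls of Nr4a1, Atf3, Zbtb17, Mast3, Recql5, Sema6b, Maf1, Nab1, Nab2, Dusp16, Xbp1, Pdia6, Msmo1, Hsph1, Cdkn1a and Syt4 were lost (adjusted p up to 0.426). Leaving out 2 pulses 100 nM A, 4 pulses 10 nM C or 2 pulses 100 nM D lost the call of Pdia6 (adjusted p up to 0.0572).

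Of the 29 immediate early genes 13 rose with pulse number at 10 nM, or 19 adjusted over the list alone (camera adjusted p = 1.08e-25, adjusted p = 0.00962 with an estimated correlation), with Atf3 at 0.72 ± 0.16. Of 17 feedback regulators 4 rose, among them Dusp16 (0.44 ± 0.10), or 7 adjusted over the list alone (camera adjusted p = 8.15e-08, adjusted p = 0.00962 with an estimated correlation). In the unfolded protein response 4 of 19 rose, among them Xbp1 (0.29 ± 0.06) and Pdia6 (0.37 ± 0.09), or 11 adjusted over the list alone (camera adjusted p = 8.67e-11, adjusted p = 0.00838 with an estimated correlation). The cytoskeletal list had 3 risen of 22, among them Tpm1 (0.46 ± 0.06) and Tpm4 (0.36 ± 0.05), or 4 adjusted over the list alone (camera adjusted p = 5.82e-05, adjusted p = 0.00838 with an estimated correlation). The heat shock list had 1 risen of 11, Hsph1 (0.32 ± 0.06), or 4 adjusted over the list alone (camera adjusted p = 7.2e-06, adjusted p = 0.0147 with an estimated correlation). In cholesterol synthesis 3 rose, Idi1 (0.56 ± 0.06), Msmo1 (0.38 ± 0.08) and Cyp51 (0.36 ± 0.06), or 5 risen and 1 fallen adjusted over the list alone. The call was lost (camera adjusted p = 2.62e-05, adjusted p = 0.141 with an estimated correlation). Cdkn1a (0.59 ± 0.11) and Syt4 (0.37 ± 0.07) rose as well. In the interferon list limma put 0 of 9 past the threshold, or 2 fallen adjusted over the list alone, and the call (camera adjusted p = 0.0425, adjusted p = 0.141 with an estimated correlation) was lost. In the test of the difference between the trends of the doses limma found 1 probe set, Serpinb2 (6 probe sets with the letter as a fixed and 7 as a random block), with 410 at an unadjusted p under 0.05 where chance gives about 425. No list call of this difference held with an estimated correlation, with the lowest adjusted p = 0.0764, for the cytoskeletal list. Leaving out 1 pulse 100 nM A, 8 pulses 10 nM B, 1 pulse 10 nM B, 8 pulses 10 nM C, 1 pulse 10 nM C, 8 pulses 100 nM D or 1 pulse 100 nM D lost the call of Serpinb2 (adjusted p up to 0.118). It was lost with array medians set equal too (adjusted p = 0.0537; 0.0014 to 1 over all alternatives).

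Tonic GnRH was set against 8 pulses, continuous against frequent pulsed delivery, over both doses (4 arrays against 4). No single gene passed. The characteristics call 8 pulses 100 nM D constant, and tonic 100 nM D and tonic 10 nM C 1 pulse. These entries are part of the repeated order described in the processing, so they are no separate evidence against the titles. If 8 pulses 100 nM D was in truth tonic, this contrast would be drawn toward 0. The 100 nM side of this contrast thus depends on the title of that array. At 10 nM alone, a contrast without that array chosen after the data were seen, limma also found 0 probe sets. There 220 had an unadjusted p under 0.05. The smallest p were those of Ier3, an early response gene (0.98 ± 0.16, adjusted p = 0.0833), Pstk (-0.75 ± 0.15, adjusted p = 0.153) and Apoc2 (0.84 ± 0.17, adjusted p = 0.153). Ier3 passed with the letter as a fixed block (adjusted p = 0.00738) or a random block (adjusted p = 0.0107), and without 1 pulse 10 nM B (0.0452), 1 pulse 10 nM C (0.0447), tonic 10 nM C (0.0328) or 8 pulses 100 nM D (0.0243). The adjusted p of Ier3 ran from 0.00738 to 1 over all alternatives. Egr1 was at 0.29 ± 0.27, Nab1 at -0.18 ± 0.16, Nab2 at 0.06 ± 0.14, Lhb at 0.03 ± 0.14, Cga at 0.06 ± 0.14 and Gnrhr at -0.50 ± 0.18 (adjusted p = 0.911). As lists, cytoskeletal genes were higher with tonic GnRH (median 0.172; camera adjusted p = 2.95e-07, adjusted p = 0.00237 with an estimated correlation), with 0 members past the threshold and 2 adjusted over the list alone. Heat shock proteins were lower (median -0.277; camera adjusted p = 1.8e-06, adjusted p = 0.0246 with an estimated correlation), with 0 members and 3 adjusted over the list alone. The 8 pulse array A at 100 nM had the highest Gapdh ratio (1.69), against 0.955 to 1.07 on the tonic arrays. In fits chosen after the data were seen, without this array the heat shock call was lost with the estimate (median -0.235; camera adjusted p = 7.87e-05, adjusted p = 0.0636 with an estimated correlation). The cytoskeletal call was kept (adjusted p = 1.05e-05 and 0.00988). At 10 nM alone both calls passed (heat shock median -0.426, adjusted p = 2.76e-06 and 0.0265; cytoskeletal median 0.222, adjusted p = 2.76e-06 and 0.00488). Over all arrays, calls lost with the estimate were those of immediate early genes (4 risen adjusted over the list alone; camera adjusted p = 8.52e-11, adjusted p = 0.141 with an estimated correlation), feedback regulators (camera adjusted p = 0.00995, adjusted p = 0.21 with an estimated correlation), ribosomal proteins (camera adjusted p = 0.00605, adjusted p = 0.513 with an estimated correlation; adjusted p = 0.851 with quantile normalisation) and other cell types (camera adjusted p = 0.0474, adjusted p = 0.389 with an estimated correlation). Limma found 0 probe sets, with 415 at an unadjusted p under 0.05 where chance gives about 425, and 0 for the difference of this contrast between the doses, with 181.

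Over the 4 patterns given at both doses, 100 nM was set against 10 nM (8 arrays against 8). Mmp12 was higher at 100 nM by 2.07 ± 0.17 (adjusted p = 1.01e-06), Egr1 by 1.65 ± 0.19, the transcription factor Klf4 by 1.55 ± 0.11, and Sema3e by 1.41 ± 0.19. Srxn1 was higher by 1.41 ± 0.13, Serpinb2 by 1.38 ± 0.17, the neurofilament gene Nefm by 1.37 ± 0.12 and Csf2rb2 by 1.33 ± 0.13. Ash2l (-0.98 ± 0.24), the checkpoint gene Rad1 (-0.95 ± 0.19), Pdia4 (-0.94 ± 0.15), Bnip3 (-0.92 ± 0.15), Nsdhl (-0.91 ± 0.19) and Dnph1 (-0.91 ± 0.11) were lower. Nab1 (0.44 ± 0.11) and Nab2 (0.35 ± 0.10) were higher, and Lhb (-0.25 ± 0.10), Cga (0.22 ± 0.10) and Gnrhr (0.06 ± 0.13) did not pass. With array medians set equal Lhb passed as lower (-0.284, adjusted p = 0.0274), as it did without 8 pulses 100 nM A, 4 pulses 100 nM A, 4 pulses 10 nM B or tonic 10 nM C (adjusted p up to 0.049; 0.0274 to 0.425 over all alternatives). Cga passed without 8 pulses 100 nM D (adjusted p = 0.0453), and its second probe set passed as higher (0.35 ± 0.09, adjusted p = 0.00939; 0.00939 to 0.903 over all alternatives), while with quantile normalisation Cga was at 0.0103. Second probe sets of Egr1 (0.016 ± 0.20), Srxn1 (0.00263 ± 0.12), Acvr2a (0.28 ± 0.11) and Cdk4 (-0.48 ± 0.19) and 1 of 2 further ones of Plk1 (-0.22 ± 0.09) did not pass. Of 8491 probe sets 2005 passed, 927 higher and 1078 lower; with array medians set equal the split was 719 and 1259. The letters A and D were 100 nM and B and C 10 nM throughout, so dose and letter cannot be separated. Dose thus varied only between letters, while limma counted arrays as the units, also with the letter as a random block. Its adjusted p for this comparison can therefore be too small. The Gapdh ratio was raised on 3 of the 100 nM arrays (1.69, 1.21 and 1.23). Without these the count fell, in a comparison without 4 pulses at either dose and with array D alone for 8 pulses at 100 nM. Ash2l, Nsdhl, Nab1, Nab2, Acvr2a, Prkca, Ddit3, Cdkn1a, Plk1, Tubb3, Tubb5 and Pfn1 then lost their calls. Leaving out 8 pulses 100 nM A, 4 pulses 100 nM A, 1 pulse 100 nM A, tonic 100 nM A, 4 pulses 10 nM B, tonic 10 nM B, 8 pulses 10 nM C or 1 pulse 10 nM C lost the call of Nab2 or Tubb3 (adjusted p up to 0.0735). With the letter as a random block, the only block that can be fitted across doses, 1139 probe sets passed, and Nab2 (adjusted p = 0.0842) and Tubb3 (adjusted p = 0.0626) lost their calls (2.83e-04 to 0.949 over all alternatives).

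Of the 29 immediate early genes 20 were higher at 100 nM, or 24 adjusted over the list alone, among them Fosl1 (1.25 ± 0.12). The call was lost with the estimate (camera adjusted p = 6.39e-15, adjusted p = 0.0642 with an estimated correlation). Of 17 feedback regulators 13 were higher, or 14 adjusted over the list alone (camera adjusted p = 2.85e-08, adjusted p = 0.0224 with an estimated correlation), with Rgs2 at 1.28 ± 0.15 and Dusp1 at 0.94 ± 0.13. The cytoskeletal list had 10 higher and 3 lower of 22, the same numbers adjusted over the list alone (camera adjusted p = 0.00252, adjusted p = 0.0348 with an estimated correlation). Tpm1 (0.72 ± 0.09) and Krt18 (0.65 ± 0.12) were higher, and the tubulins Tubb3 (-0.50 ± 0.16) and Tubb5 (-0.37 ± 0.10) and profilin, Pfn1 (-0.50 ± 0.12), which were chosen after their values were seen, were lower. Heat shock genes were higher in 5 of 11, or 6 adjusted over the list alone, and the call was lost (camera adjusted p = 0.00252, adjusted p = 0.096 with an estimated correlation). Of ribosomal protein genes 1 was higher, also 1 adjusted over the list alone, and that call was lost as well (camera adjusted p = 0.029, adjusted p = 0.61 with an estimated correlation), and also with quantile normalisation (adjusted p = 0.69) and array medians set equal (adjusted p = 0.0581). The lists that follow had no camera call. Genes of GnRH receptor signalling were higher in 4 of 25 and lower in 0, and interferon response genes higher in 0 of 9 and lower in 4, the same numbers adjusted over the list alone (camera adjusted p = 0.19 and 0.377). In cholesterol synthesis 6 were lower, among them Mvd (-0.66 ± 0.11), and Idi1 was higher (0.84 ± 0.09), or 7 and 3 adjusted over the list alone. In the cell cycle list 9 were lower, among them Cdk4 (-0.47 ± 0.08) and Plk1 (-0.47 ± 0.09), and 3 higher, among them the inhibitor Cdkn1a (0.83 ± 0.16), or 12 and 3 adjusted over the list alone. Of gonadotrope genes 4 were lower, among them Inhbb (-0.85 ± 0.14) and Pitx1 (-0.46 ± 0.10), and 3 higher, among them the activin receptor gene Acvr2a (0.52 ± 0.14), or 5 and 3 adjusted over the list alone. Ppp1r15a (0.78 ± 0.15), Ddit3 (0.65 ± 0.18), Prkca (0.49 ± 0.11) and Cd68 (0.93 ± 0.16) were higher as well. The unfolded protein response list of Ppp1r15a and Ddit3 moved both ways, as Pdia4, named above, and Pdia6 (-0.51, limma adjusted p = 0.0135) were lower. Further probe sets of Pdia6 gave -0.72, which passed, and 0.05, which did not.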

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

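The label tests, and the tests of time since the last pulse and of a difference shared by letters, were chosen only after the results were seen, and so were the fit without the 3 arrays of highest Gapdh ratio and the look at which split gave 78 probe sets. The reading of the splits of the tonic arrays was changed to say nothing about chance after its result was seen. The rules for reading the letter ratio and the RNA quality test were revised toward caution after their results were seen.

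Serpinb2 had slopes of 1.17 ± 0.11 per doubling at 100 nM and 0.08 ± 0.11 at 10 nM, and the difference of 1.08 ± 0.16 passed the test between doses (adjusted p = 0.016; 0.0537 and so lost with array medians set equal; 0.0014 to 1 over all alternatives). Its signals were 2027 and 3257 with 8 pulses at 100 nM and 62.1 and 64.4 with 1 pulse at 100 nM. At 10 nM they were 197 and 219 with 1 pulse, 40.4 and 201 with 4 pulses, and 289 and 374 with 8 pulses. With tonic 10 nM they were 1062 and 1069, and unstimulated 147 and 222. The signals under 150 lie below the added constant of 166.8, and the probe set carries a suffix for shared probes. Leaving out 1 pulse 100 nM A, 8 pulses 10 nM B, 1 pulse 10 nM B, 8 pulses 10 nM C, 1 pulse 10 nM C, 8 pulses 100 nM D or 1 pulse 100 nM D lost the call of Serpinb2 (adjusted p up to 0.118).

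The labels of 8 arrays name different patterns in the title and in the characteristics. Of 6 arrays other than 8 pulses 100 nM D for which both could be compared, 0 correlated more with the array their characteristics name, which argues against the characteristics there. The median residual standard deviation was 0.228 with title groups and 0.291 with characteristics groups. The array 8 pulses 100 nM D correlated more with tonic 100 nM A (0.974) than with 8 pulses 100 nM A (0.963), a difference of 0.0107. In the characteristics, the entry of this array is part of the repeated order described in the processing. That entry is therefore no separate evidence against the title. The correlation alone cannot exclude a wrong title. The reason is that limma found 0 probe sets between tonic and 8 pulses, with 415 at an unadjusted p under 0.05. The array 8 pulses 100 nM A had the highest Gapdh 3' to 5' ratio (1.69), against 1.02 on tonic 100 nM A and 0.985 on 8 pulses 100 nM D. Its RNA quality was not tested as a source of the lower correlation. No biological explanation was tested.

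For the 585 probe sets that changed with pulse number at 100 nM, the median slope at 10 nM, signed by direction, was 54.8% of that at 100 nM (53.8% with letter B and 60.8% with C). At 10 nM the Gapdh ratio stays between 0.900 and 1.01, and the actin ratio did not rise with pulse number there. It was even with B (2.34, 2.42 and 2.23 for 1, 4 and 8 pulses) and fell with C (3.64, 2.83 and 2.77). This argues against RNA quality as the whole cause, while the count of 247 without the 3 arrays of highest ratio, a fit with fewer arrays, leaves a part open. Time since the last pulse changes with pulse number for all 585, and pulse number and delay cannot be told apart, as no group has the same number with another delay. A response to pulse frequency is a candidate explanation that stays open beside it.

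For the 2005 probe sets between 100 nM and 10 nM, 1 of 100 splits of the 16 arrays, the real one, gave as many (2134 in that model, at most 1 in the others). These splits treat arrays as independent, but arrays share letters and dose varies only between letters, so they cannot exclude chance. The 3 ways to pair the letters are too few for a share under 0.05. The median absolute difference between doses was 1.60 times that between letters of a dose (1.54 with A and D, 1.65 with B and C), while splitting the letters as A and B against C and D gave 0 probe sets and as A and C against B and D gave 14. That ratio is over the bound of 1.5 set beforehand to exclude separate letter effects, but 4 letters give only 3 pairings and so no error for the ratio, which leaves this open. A difference shared by A and D against B and C for any of the 2005 cannot be told apart from dose, since no dose was given to both. Signed by direction, the median 100 nM minus 10 nM difference of the 2005 was 0.353 for 1 pulse and 0.555 for 4 pulses. It was 0.425 for 8 pulses and 0.402 for tonic GnRH. The 2005 were chosen and signed on the mean over these patterns, so positive values in single patterns follow largely from that choice. After 1 pulse limma found 0 probe sets against unstimulated cells at either dose. The 1 pulse value therefore cannot show a difference already present there, and none of these values can separate dose from letter. A dose response is a candidate explanation that stays open.

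For tonic against 8 pulses, 34 of the 34 splits of the 8 arrays that could be fitted gave at least as many probe sets as the real 0, an outcome that a real count of 0 fixes, so this says nothing about chance. The highest of the others gave 78, and that split parts the letters A and C from B and D, while the other split along letters, A and B against C and D, gave 0. The 78 point to a structure of these arrays other than the pattern, whose source was not tested. With the letter as a fixed block limma found 1 probe set, Ier3, with 729 at an unadjusted p under 0.05.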

How the results depend on the processing

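The fit without the 3 arrays of highest Gapdh 3' to 5' ratio was chosen only after the data were seen. It has no 4 pulse array at 100 nM and only array D of 8 pulses there. So 4 pulses left the mean of all 100 nM patterns, the trend at 100 nM and both sides of 100 against 10 nM. Its counts are therefore not for the same comparisons. Counts of probe sets past the threshold were 1207 (all 100 nM patterns), 162 (all 10 nM patterns), 0 (1 pulse at 100 nM), 53 (2 pulses at 100 nM), 1268 (4 pulses at 100 nM), 1215 (8 pulses at 100 nM), 1735 (tonic 100 nM), 0 (1 pulse at 10 nM), 5 (4 pulses at 10 nM), 189 (8 pulses at 10 nM), 629 (tonic 10 nM), 585 (the trend at 100 nM), 178 (the trend at 10 nM), 1 (the trend difference), 0 (tonic against 8 pulses), 0 (its difference between doses), 2005 (100 against 10 nM). Counts not given below stayed within 1.5 times these, and the cause of the shifts was not tested except that the 12 arrays with agreeing labels and the compared groups leave fewer arrays, and the 12 arrays only 2 residual degrees of freedom. With these 12 the counts were 146 for all 100 nM patterns, 11 for all 10 nM patterns, 0 for 2 pulses at 100 nM, 46 for 4 pulses at 100 nM, 278 for 8 pulses at 100 nM, 371 for tonic 100 nM, 2 for 4 pulses at 10 nM, 50 for 8 pulses at 10 nM, 174 for tonic 10 nM, 72 for the trend at 100 nM, 13 for the trend at 10 nM and 0 for the trend difference. With the compared groups only they were 10 for 2 pulses at 100 nM, 801 for 4 pulses at 100 nM, 461 for 8 pulses at 100 nM, 0 for 4 pulses at 10 nM, 74 for 8 pulses at 10 nM, 289 for tonic 10 nM, 295 for the trend at 100 nM and 0 for the trend difference. With groups from the characteristics (19 arrays) they were 0 for all 100 nM patterns, 0 for all 10 nM patterns, 0 for 2 pulses at 100 nM, 0 for 4 pulses at 100 nM, 0 for 8 pulses at 100 nM, 0 for tonic 100 nM, 0 for 4 pulses at 10 nM, 0 for 8 pulses at 10 nM, 0 for tonic 10 nM, 0 for the trend at 100 nM, 0 for the trend at 10 nM, 0 for the trend difference and 0 for 100 against 10 nM, with 72 to 1054 at an unadjusted p under 0.05 in limma. With the letter as a fixed block, not run across doses since letter and dose go together, they were 1872 for all 100 nM patterns, 21 for 1 pulse at 100 nM, 136 for 2 pulses at 100 nM, 1962 for 4 pulses at 100 nM, 1843 for 8 pulses at 100 nM, 1104 for the trend at 100 nM, 464 for the trend at 10 nM, 6 for the trend difference and 1 for tonic against 8 pulses. As a random block they were 14 for 1 pulse at 100 nM, 107 for 2 pulses at 100 nM, 972 for the trend at 100 nM, 413 for the trend at 10 nM, 7 for the trend difference, 1 for tonic against 8 pulses and 1139 for 100 against 10 nM. Without a filter they were 103 for all 10 nM patterns, 23 for 2 pulses at 100 nM and 0 for the trend difference. Without an intensity trend they were 90 for all 10 nM patterns, 16 for 2 pulses at 100 nM and 1 for tonic against 8 pulses. With quantile normalisation they were 12 for 1 pulse at 100 nM, 8 for 4 pulses at 10 nM and 2 for the trend difference. With equal medians they were 35 for 2 pulses at 100 nM, 9 for 4 pulses at 10 nM and 0 for the trend difference. Without the 3 Gapdh arrays they were 716 for 8 pulses at 100 nM, 247 for the trend at 100 nM, 5 for the trend difference and 660 for 100 against 10 nM; the contrast of 4 pulses at 100 nM could not be fitted. Leaving out 1 array gave 363 to 1354 (all 100 nM patterns), 34 to 226 (all 10 nM patterns), 0 to 3 (1 pulse at 100 nM), 11 to 53 (2 pulses at 100 nM), 203 to 1393 (4 pulses at 100 nM), 611 to 1237 (8 pulses at 100 nM), 1086 to 1850 (tonic 100 nM), 0 to 2 (1 pulse at 10 nM), 0 to 26 (4 pulses at 10 nM), 62 to 208 (8 pulses at 10 nM), 175 to 694 (tonic 10 nM), 250 to 629 (the trend at 100 nM), 39 to 206 (the trend at 10 nM), 0 to 4 (the trend difference), 0 to 1 (tonic against 8 pulses), 0 to 0 (its difference between doses) and 1537 to 2229 (100 against 10 nM). A group left with 1 array is assumed there to vary like the other groups.

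Of 214 gene values, 208 kept direction and side of the threshold with quantile normalisation, 207 with equal medians, 210 with the floor, 208 with the random block, 122 with the 12 arrays and 33 with characteristics groups. With the characteristics groups all 181 called values lost their call, and 19 of them changed sign. For all 100 nM patterns these were Recql5 0.079, Inhbb 0.063, Dnajc3 -0.021, Manf -0.067, Pdia4 0.082 and Rpl22 0.055. For all 10 nM patterns these were Syt4 -0.094. For the trend at 100 nM these were Serpinb2 -0.15, Angpt2 -0.018, Crem -0.025, Ier3 -0.073, Nr0b1 0.021, Pitx1 0.041, Syt4 -1.25e-04, Prkce 0.044, Cdkn1a -0.11, Ndrg1 -0.052, Krt18 -0.074 and Tpm4 -0.00938. Cga over all 100 nM patterns was -0.00115 with quantile normalisation. Other probe sets changed sign for Rpl22 over all 100 nM patterns (0.45), Egr1 in the trend at 100 nM (-0.066) and with tonic 100 nM (-0.42), and Srxn1 in the trend at 10 nM (-0.024). The mean of ribosomal proteins in tonic against 8 pulses was -0.029 with quantile normalisation. Of 181 called gene values, 81 lost their call in at least 1 of the runs that left out 1 array and 0 changed sign. Of the list calls in the comparisons over all patterns of a dose, the 2 trends, tonic against 8 pulses and 100 against 10 nM, 22 were lost with an estimated correlation. Signals near the added constant of 166.8 limit what low probe sets can show.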

Other observations

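All 7 lists in this part and their tests were chosen only after the first results were seen, and the rule for reading the p53 list was revised toward caution after its own result. In 100 nM against 10 nM (8 arrays against 8), 12 of 38 genes of the mitochondrial respiratory chain, which makes ATP, were lower at 100 nM and 1 was higher (camera adjusted p = 0.0323, adjusted p = 0.655 with an estimated correlation, so the call was lost). Against unstimulated cells the median of this list was 0.216 at 10 nM, with 0 members past the threshold (camera adjusted p = 8.17e-04, adjusted p = 0.503 with an estimated correlation, lost), and 0.05 at 100 nM, with 2 risen and 3 fallen (camera adjusted p = 0.417). The integrated stress and amino acid response had 2 of 21 genes rising with pulse number at 10 nM (camera adjusted p = 3.33e-05, adjusted p = 0.127 with an estimated correlation, lost). Of 31 proteasome genes 1 rose and 1 fell over all 100 nM patterns (camera adjusted p = 0.417), of 14 circadian clock genes 1 rose and 2 fell (adjusted p = 0.646), and of 22 genes of the nucleolus 2 rose (adjusted p = 0.332). Over all 10 nM patterns camera called the proteasome list up (1 risen, median 0.0814; camera adjusted p = 0.0135, adjusted p = 0.503 with an estimated correlation) and the integrated stress list (0 risen, median 0.125; camera adjusted p = 0.00298, adjusted p = 0.467), and both calls were lost. In the trend at 10 nM the call of the respiratory chain was lost (median -0.0606; camera adjusted p = 0.0255, adjusted p = 0.504).

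Srxn1 is a known target of the oxidative stress factor Nrf2, and Cdkn1a of p53. Of 17 other Nrf2 targets 2 rose and none fell over all 100 nM patterns, with a median of 0.01 (camera adjusted p = 0.526 with an estimated correlation). This median argues against a joint rise of the list as a whole, while a rise of single members with Srxn1 stays open. In 100 nM against 10 nM 4 of the 17 were higher and 2 lower (median 0.01; camera adjusted p = 0.543). Over all 100 nM patterns 3 of 12 other p53 targets rose and 1 fell, with a median of -0.03 and a mean of 0.22 (camera adjusted p = 0.753 with an estimated correlation). As they moved both ways, this test leaves a part for p53 open. In 100 nM against 10 nM 6 of the 12 were higher and 1 lower (median 0.372; camera adjusted p = 0.00617, adjusted p = 0.645 with an estimated correlation, so the call was lost), and in the trend at 10 nM 2 rose (camera adjusted p = 0.0237, adjusted p = 0.339, lost).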
